A study of Rattus norvegicus with 47 samples.

How the data were processed

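The series holds 47 single-colour Affymetrix rat arrays of liver RNA from 3 experiments, with 20, 16 and 11 arrays in 13 groups. The deposited table holds log2 signal values for 31099 probe sets, made per the submitters' processing notes with GCOS (version not given). Each array is centred on a median of 0 and has 1 floor value that its lowest probe sets share. The deposited signal was assumed to be linear when the tests were planned and was found to be on a log2 scale, so no logarithm or offset was applied, and the fold changes are differences of the deposited log2 values. Precision is limited by the number of arrays per group and by the floor: the median signal was 10.0 to 69.8 times the floor, and 5 to 3172 probe sets per array lay at it.

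Of all probe sets 20832 matched 1 gene, 436 matched several and 9831 were unnamed here. The 57 control probe sets, 51 of them unnamed, were left out, which gave 14217 named genes, with gene identifiers matched for 20764 probe sets and 0 symbols updated. Each gene was represented by the probe set with the highest mean.

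Probe sets above the 40th percentile of their own array in at least 2 arrays of an experiment were tested, which left 27595, 28869 and 22763. Each experiment was fitted on its own with limma 3.58.1 in R 4.3.3, with lmFit on group means and eBayes with an intensity trend. The diet experiment had the run of identifiers (12 arrays in the first, 8 in the second) as a covariate, since each run held deficient, marginal and adequate rats, while both supplemented arrays were in the first. Comparisons were each diet with adequate, supplemented with deficient, a linear trend over the 4 diet levels in order, each RA time with vehicle, all RA times together, and 16 h with 3 h. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over those tested. Prior and residual degrees of freedom were 16.7 and 15, 18.4 and 11, and 7.29 and 7.

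For 29 fixed gene lists, covering metabolic and signalling groups and markers of other cell types, limma camera was run with a preset correlation of 0.01, adjusted over the lists of a contrast. Genes of each list were also adjusted over the list alone. Named genes were fixed by rule. Per contrast these were the 10 largest rises and 10 largest falls among called genes with a name, all called retinoid genes, and up to 4 called members (2 for the 16 h contrasts) of each other list that was called or had at least 3 called members. Cyp26a1, Cyp26b1, Lrat, Rarb, Dhrs3, Cyp2c22 and Cyp3a9 were named in each contrast. Genes called in the diet experiment (supplemented against deficient) were tested as sets in the RA experiments with camera, with Spearman correlations across genes beside them.

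The pipeline was tested on simulated data drawn from the mean and residual spread of each probe set in the same designs, with 100 probe sets changed at each fold. At 2-fold and 4-fold it recovered 22% and 49% in the deficient and adequate design, 1% and 28% in the 16 h design and 21% and 65% in the 90 min design, with 4.05%, 0% and 7.53% of calls on unchanged probe sets. A list of 30 probe sets shifted by 0.5 gave a camera p of 2.95e-09, 2.18e-10 and 6.58e-11.

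Alternatives tried were quantile normalization, no filter, eBayes without a trend, limma arrayWeights, a fold change of at least 1.5, the replicate number as a block, each array left out in turn, no run covariate, each run alone, the run as a random block, camera with an estimated correlation, fry, and the mean over all probe sets of a gene. Offsets on back-transformed values, and fits without arrays that stood apart (deficient replicates 1, 2 and 5, adequate replicate 5, and 16 h replicates 1 and 2), were chosen after seeing the data.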

Results

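Liver RNA of female Sprague-Dawley rats was measured on 47 single-colour Affymetrix arrays in 3 experiments, with RNA of 1 rat on each array. In the diet experiment, rats ate a purified diet from weaning to 8 weeks of age with retinol (vitamin A) at 0 mg/kg (deficient, 5 arrays), 0.4 mg/kg (marginal, 7 arrays), 4 mg/kg (adequate, 6 arrays) or 100 mg/kg (supplemented, 2 arrays). In the retinoic acid (RA) time course, vitamin A-deficient rats of 8 weeks received vehicle (3 arrays, killed at 0 h) or about 100 µg of all-trans-RA and were killed after 3 h (3 arrays), 6 h (3 arrays), 10 h (4 arrays) or 16 h (3 arrays). In the intravenous experiment, fasted rats on a stock diet were treated under light isoflurane. They received vehicle into an iliac vein (2 arrays, killed at 0 min) or about 25 µg of RA (10 µg per 100 g of body weight) and were killed after 30, 60 or 90 min (3 arrays each). The sample titles call both control groups untreated, while the treatment notes state vehicle. Values are log2 signals relative to the array median, and the number of arrays limits the precision. Errors of fold changes are standard errors (SE) from limma, errors of group means are standard deviations (SD), and a call is an adjusted p under 0.05.

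The comparison of deficient with adequate livers asked which transcripts depend on dietary vitamin A. Deficient livers had less of the retinoid transcripts Lrat, Cyp26a1 and Rarb and of the lipogenic transcripts Fasn and Scd. Lrat, which esterifies retinol for storage, fell by 2.89 ± 0.39 on the log2 scale (adjusted p = 2.72e-05), from a mean of 1.83 ± 0.15 (SD, n = 6) to -1.24 ± 1.46 (SD, n = 5). Cyp26a1, which oxidises RA, fell by 1.94 ± 0.46 (adjusted p = 0.0255), and the RA receptor gene Rarb fell by 1.28 ± 0.24 (adjusted p = 0.00303). Cyp2c22 was 23.7-fold lower (log2 change -4.57 ± 0.29, adjusted p = 6.54e-12), and Cyp3a9 was 10.2-fold lower (-3.35 ± 0.25, adjusted p = 1.84e-10). For Lrat, Cyp26a1, Cyp2c22 and Cyp3a9, 5 of 5 deficient arrays lay below all adequate arrays. Deficient replicate 3 lay at its floor for Lrat and Cyp26a1, so the size and spread of their changes against the deficient group depended partly on that floor, as for Lum on deficient replicate 4 and Hhip on adequate replicate 1. Dhrs3, a retinaldehyde reductase (-0.53 ± 0.16, adjusted p = 0.127), and Cyp26b1 (-1.59 ± 0.80, adjusted p = 0.409) were not called.

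Of 31 measured genes of lipogenesis, 12 were called lower and none higher, or 20 lower and 1 higher adjusted over the list alone, with a median change of -0.607 (camera adjusted p = 3.04e-13, and adjusted p = 0.298 with an estimated correlation). The genes of fatty acid synthase, Fasn (-2.66 ± 0.30, adjusted p = 2.12e-06), stearoyl-CoA desaturase, Scd (-3.65 ± 0.45), and acetyl-CoA carboxylase, Acaca (-1.73 ± 0.27), fell, as did Elovl6 (-2.46 ± 0.35). Pnpla3 also fell (-2.97 ± 0.59, adjusted p = 0.00465). Of 21 measured genes of cholesterol synthesis, 5 were called lower, or 11 adjusted over the list alone, and none higher (median -0.574, camera adjusted p = 2.6e-11, and adjusted p = 0.298 with an estimated correlation). They included Insig1 (-1.95 ± 0.28), Msmo1 (-1.55 ± 0.27), Acat2 (-1.27 ± 0.25) and Fdft1 (-0.86 ± 0.19). Genes of the interferon response were called lower in 7 of 41 cases, or 17 adjusted over the list alone (median -0.56, camera adjusted p = 3.81e-08, and adjusted p = 0.404 with an estimated correlation). Among them were Ifi27l2b (-1.32 ± 0.25), Psmb8 (-0.92 ± 0.18), Igtp (-1.14 ± 0.23) and Ifi44l (-1.34 ± 0.28). RA receptor targets were called lower in 4 of 23 cases, or 5 adjusted over the list alone (median -0.281, camera adjusted p = 0.0482, and adjusted p = 0.402 with an estimated correlation). They were Lrat, Rarb, Cyp26a1 and Tgm2 (-0.67 ± 0.16). Fatty acid oxidation genes lay higher as a group (median 0.106, camera adjusted p = 0.00156, and adjusted p = 0.697 with an estimated correlation), with 0 of 45 called by limma, or 0 adjusted over the list alone.

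The largest rises in deficient livers were in Cyp2a2 (16.6-fold, log2 change 4.06 ± 0.64, adjusted p = 0.000324) and in Cyp17a1, the steroid 17-alpha-hydroxylase (11.3-fold, 3.49 ± 0.42, adjusted p = 3.42e-06), in 5 of 5 arrays each. Hhip (2.61 ± 0.65), Abcg5 (2.21 ± 0.46), Serpina7 (1.98 ± 0.38), A2ml1 (1.91 ± 0.38), Rab30 (1.82 ± 0.33), Pla2g12a (1.80 ± 0.43), Sds (1.76 ± 0.33) and Prelp (1.70 ± 0.43) followed. The largest falls outside these groups were in Sult1c3 (-4.80 ± 0.55, 28.0-fold), Lum (-3.26 ± 0.74), Stac3 (-3.13 ± 0.51) and Cpa1 (-2.83 ± 0.48). Markers of pancreatic acinar cells as a group did not differ (1 of 14 called lower, 1 adjusted over the list alone, median -0.193, camera adjusted p = 0.875 for a shift upward). Among 25 drug-metabolising P450 and other CAR or PXR genes, 1 rose and 4 fell, or 3 and 8 adjusted over the list alone. The group was not called (camera adjusted p = 0.174). Cyp2c7 fell by 1.38 ± 0.26. Of 29 bile acid genes, Abcg5 and Abcb4 (0.78 ± 0.19) rose and Nr1h4 (-1.23 ± 0.22) and Slco1b2 (-0.96 ± 0.24) fell, or 4 and 5 adjusted over the list alone (median -0.146, mean 0.0274, camera adjusted p = 0.764). In the gluconeogenesis list of 23 genes, Sds rose and Gpt2 (-1.14 ± 0.28) and Gcgr (-0.96 ± 0.24) fell, or 1 and 3 adjusted over the list alone (median -0.0664, mean 0.0143, camera adjusted p = 0.304). Cell cycle, sinusoidal endothelial and cholangiocyte genes had no called member among 35, 15 and 8, over all genes or adjusted over the list alone, and camera adjusted p-values were 0.262, 0.868 and 0.174. Conjugating enzymes were split, with 1 higher and 1 lower, Sult1c3, among 37 (2 and 3 adjusted over the list alone, median -0.037, camera adjusted p = 0.564 for a shift upward).

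In total 299 of 27595 probe sets were called, 22 higher and 277 lower. Without 1 array the count ran from 156 (adequate replicate 2) to 1493 (deficient replicate 4), and without a trend in eBayes it was 64. After quantile normalization 338 were called, 119 higher and 219 lower, and the median of all probe sets tested shifted by -0.111 between the groups. The arrays fell into 2 runs of database identifiers that each held deficient and adequate rats, and 39 of 39 called named genes had the same sign within each run, which their selection over both runs favoured. Cyp2c22 changed by -3.39 in the first run and -5.78 in the second, Fasn by -2.62 and -2.75, and Cyp17a1 by 4.78 and 1.98. The median of the lipogenesis genes was -0.322 in the first run and -1.083 in the second, that of the interferon genes -0.166 (adjusted p = 0.121, limma camera) and -1.223, and that of the fatty acid oxidation genes 0.427 and -0.203. The runs disagreed on Kupffer cell markers, which lay higher in the first (median 0.339, camera adjusted p = 0.00363) and lower in the second (median -0.762, camera adjusted p = 0.018). Without deficient replicates 1, 2 and 5 and adequate replicate 5, which stood apart from the other arrays, 86 were called. The 3' to 5' log2 difference of GAPDH was 1.37 on adequate replicate 5 and 0.92 on deficient replicate 5, against at most 0.54 on the other diet arrays. That of actin was 3.16 on adequate replicate 5, against at most 2.10.

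**Figure D1:**
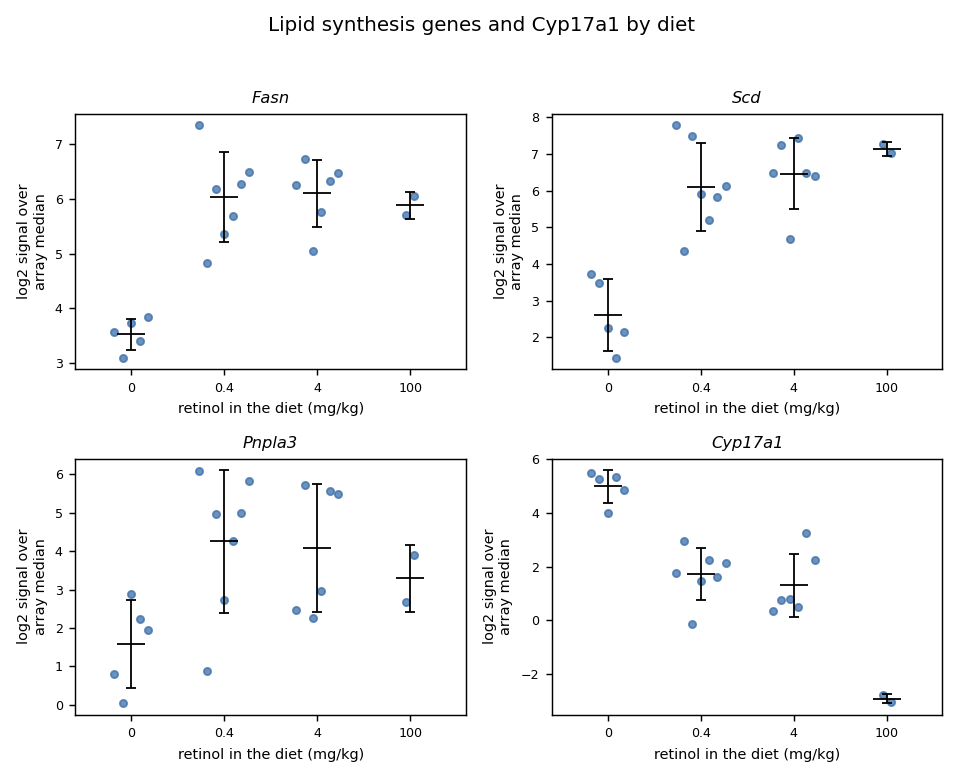
Log2 signal relative to the array median of Fasn, Scd, Pnpla3 and Cyp17a1 against dietary retinol (mg/kg), with points for arrays and bars for the group mean and SD. The deficient arrays average 3.52 for Fasn against 6.10 in adequate rats.

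Marginal and adequate livers, compared to find effects of a low but not absent supply, could not be told apart gene by gene. None of the retinoid genes named here was called: Lrat differed by -0.12 ± 0.35, Rarb by 0.20 ± 0.22, Dhrs3 by -0.08 ± 0.15, Cyp26a1 by -0.52 ± 0.41, Cyp2c22 by -0.34 ± 0.27 and Cyp3a9 by -0.52 ± 0.23 (adjusted p = 1 for each, 7 against 6 arrays). Cyp26b1 differed by more, with a large error and 1 marginal array at its floor (-1.33 ± 0.72, adjusted p = 1), so a difference of this size was not resolved. With limma 0 of 27595 probe sets were called, and 916 had an unadjusted p under 0.05. The cholesterol synthesis genes lay lower as a group (median -0.101), as did pancreatic acinar markers (median -0.293), both with camera adjusted p = 0.0283. No member of either was called, over all genes or adjusted over the list alone. With an estimated correlation, adjusted p was 0.938 and 0.754, and in the second run of arrays the cholesterol median was -0.068. In that run interferon (median -0.466, camera adjusted p = 4.85e-07) and lipogenesis genes (median -0.253, camera adjusted p = 0.000335) lay lower, while in the first their medians were 0.212 and 0.118 (camera adjusted p = 0.419 for both).

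Supplemented livers, set against adequate ones to find responses to excess vitamin A, differed in Cyp26a1 and Cyp17a1. Cyp26a1 was 20.5-fold higher (4.35 ± 0.62, adjusted p = 0.000729), with means of 4.76 ± 0.68 (SD, n = 2) against 0.38 ± 0.45 (SD, n = 6). Cyp17a1 fell by 4.00 ± 0.56 (adjusted p = 0.000729), and both genes lay beyond all adequate arrays in 2 of 2 supplemented arrays. The remaining called probe set matched the RNA helicase gene Ddx19b, which was named after its value was seen because so few were called (-4.04 ± 0.65, adjusted p = 0.00537), and it was not the probe set chosen to represent that gene. Cyp3a9 (1.10 ± 0.34), Cyp2c22 (0.94 ± 0.40), Lrat (0.91 ± 0.52), Cyp26b1 (1.79 ± 1.08), Rarb (0.24 ± 0.33) and Dhrs3 (0.14 ± 0.22) were not called (adjusted p = 1 for each). The split was 1 higher and 2 lower of 3 called, and 1 higher and 3 lower of 4 after quantile normalization. No gene list was called, and both supplemented arrays were in the first run.

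The widest contrast in supply, supplemented against deficient, gave the largest changes of the diet experiment. Sult1c3 rose by 7.80 ± 0.78 (adjusted p = 1.29e-07) and Cyp26a1 rose by 6.30 ± 0.65 (adjusted p = 2.57e-07, with 1 deficient array at its floor), in 2 of 2 supplemented arrays each. Cyp2c22 rose by 5.51 ± 0.42, Cyp3a9 by 4.45 ± 0.36, Stac3 by 4.23 ± 0.72, Scd by 4.08 ± 0.64 and Lrat by 3.80 ± 0.55. Rises followed in Lifr (3.73 ± 0.69), Car2 (3.01 ± 0.53), Adss1 (2.74 ± 0.47) and Rarb (1.51 ± 0.35, adjusted p = 0.0349). Cyp17a1 fell by 7.49 ± 0.60 (adjusted p = 8.94e-10), to near the floor on both supplemented arrays, and Cyp2a2 (-4.55 ± 0.92), Abcg5 (-3.33 ± 0.66), Cela1 (-3.11 ± 0.68), Sds (-2.70 ± 0.47) and Rab30 (-2.54 ± 0.47) fell too. Smaller falls were seen in Gadd45g (-2.05 ± 0.47), Cyp8b1 (-1.72 ± 0.32), Fabp7 (-1.64 ± 0.31) and Gstm2 (-1.54 ± 0.32). Cyp26b1 (3.37 ± 1.15, adjusted p = 0.303) and Dhrs3 (0.68 ± 0.23, adjusted p = 0.319) were not called.

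Lipogenesis genes were called higher in 5 of 31 cases, or 16 higher and 2 lower adjusted over the list alone (median 0.808, camera adjusted p = 2.76e-07, and adjusted p = 0.514 with an estimated correlation). Fasn stood at 2.55 ± 0.43, Acaca at 2.17 ± 0.38 and Mid1ip1 at 1.40 ± 0.28. Cholesterol synthesis genes lay higher (median 0.595, camera adjusted p = 1.02e-05), with Insig1 called (2.20 ± 0.40), or 4 adjusted over the list alone. Interferon genes lay higher (median 0.506) and fatty acid oxidation genes lower (median -0.351), both with camera adjusted p = 3.92e-05. Of the former none were called, or 5 higher and 1 lower adjusted over the list alone, and of the latter Eci1 fell by 1.31 ± 0.29, or 4 adjusted over the list alone. B cell markers lay lower (median -0.479, camera adjusted p = 0.0284) with none called, also adjusted over the list alone. The adjusted p with an estimated correlation was 0.514 for cholesterol synthesis and B cells, 0.716 for interferon and 0.623 for oxidation. Nr1h4 rose by 1.42 ± 0.31. In total 116 probe sets were called, 97 higher and 19 lower, against 170 after quantile normalization (108 higher and 62 lower). The median of all probe sets shifted by 0.160. Without the arrays that stood apart 58 were called, and without a trend in eBayes 20. Without 1 array the count ran from 43 (supplemented replicate 1) to 430 (deficient replicate 4), and the supplemented group held 2 arrays.

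Over the diet levels in order, from deficient to supplemented, a linear trend was fitted, which a step at a single level can also give. Sult1c3 rose by 2.42 ± 0.24 per level (adjusted p = 1.14e-07), Cyp26a1 by 1.94 ± 0.20, Cyp2c22 by 1.69 ± 0.13, Cyp3a9 by 1.39 ± 0.11 and Lrat by 1.15 ± 0.17, over 20 arrays. Stac3 (1.28 ± 0.22), Scd (1.25 ± 0.20), Lifr (1.10 ± 0.21), Car2 (0.92 ± 0.16) and Adss1 (0.85 ± 0.15) rose as well. Cyp17a1 fell by 2.28 ± 0.18 per level (adjusted p = 1e-09). Cyp2a2 (-1.50 ± 0.28), Cela1 (-0.92 ± 0.21), Sds (-0.84 ± 0.15), Rab30 (-0.75 ± 0.15), Cyp8b1 (-0.52 ± 0.10), Gstm2 (-0.52 ± 0.10) and Fabp7 (-0.51 ± 0.09) fell less steeply, and Abcg5 fell by 1.00 ± 0.20. Rarb (0.43 ± 0.11, adjusted p = 0.071), Cyp26b1 (1.15 ± 0.35, adjusted p = 0.244) and Dhrs3 (0.21 ± 0.07, adjusted p = 0.355) were not called.

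Of the lists, lipogenesis had a positive trend, with 5 of 31 called, among them Fasn (0.77 ± 0.13), Acaca (0.67 ± 0.12) and Elovl6 (0.76 ± 0.16), or 15 higher and 2 lower adjusted over the list alone (median 0.235, camera adjusted p = 1.7e-07, and adjusted p = 0.486 with an estimated correlation). The deficient group set this trend: Fasn averaged 3.52, 6.03, 6.10 and 5.88 over the levels. The list median was 0.000527 for marginal and -0.146 for supplemented against adequate. Insig1 (0.67 ± 0.12) was called among the cholesterol genes, or 5 adjusted over the list alone (median 0.187, camera adjusted p = 1.09e-06). Cyp26a1 and Lrat were called among the RA receptor targets, or 5 higher and 1 lower adjusted over the list alone (median 0.105, camera adjusted p = 0.0312). Interferon genes lay higher with none called, or 5 and 1 lower adjusted over the list alone (median 0.16, camera adjusted p = 1.74e-05). Fatty acid oxidation genes lay lower (0 called, 4 lower adjusted over the list alone, median -0.11, camera adjusted p = 0.000107), as did B cell markers (none called, also adjusted over the list alone, median -0.2, camera adjusted p = 0.0204). Acute phase genes lay lower (median -0.0632, camera adjusted p = 0.0394), although Orm1 rose by 0.65 ± 0.11, with 1 higher and 1 lower adjusted over the list alone. Adjusted p was, with an estimated correlation, 0.486 for the cholesterol, RA receptor target and B cell lists, 0.637 for interferon and oxidation and 0.929 for the acute phase. Nr1h4 rose by 0.44 ± 0.10. In total 99 probe sets were called, 85 higher and 14 lower, against 166 (102 higher and 64 lower) after quantile normalization, 61 without the arrays that stood apart and 19 without a trend in eBayes. Without 1 array the count ran from 46 (supplemented replicate 1) to 323 (deficient replicate 4).

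**Figure D2:**
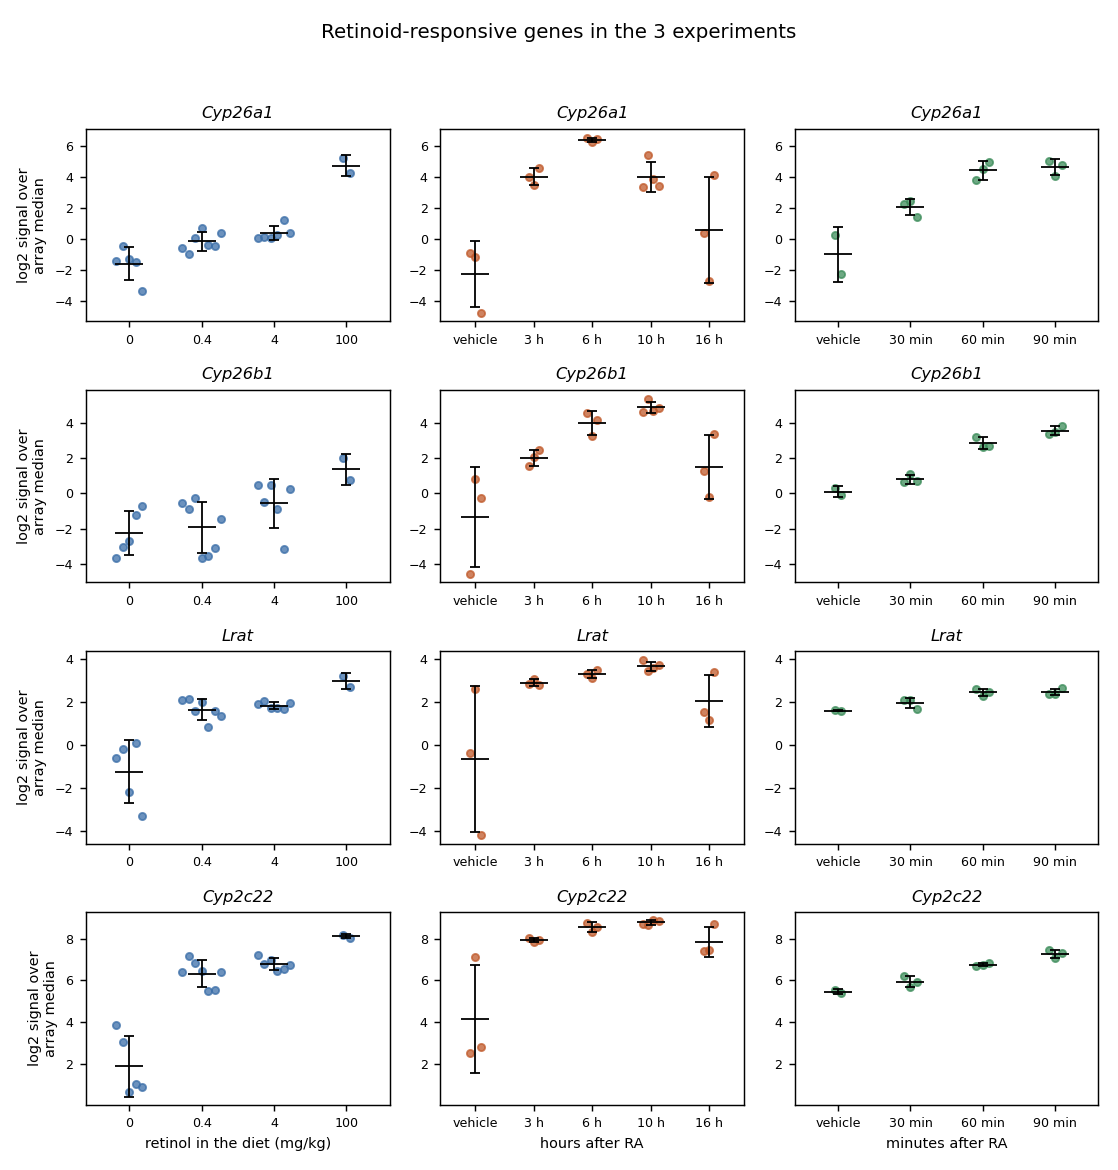
Log2 signal relative to the array median of Cyp26a1, Cyp26b1, Lrat and Cyp2c22 in the 3 experiments, against dietary retinol (mg/kg), hours after RA and minutes after RA, with points for arrays and bars for the mean and SD, where levels are comparable within a column of panels and not between columns. Cyp26a1 averages 6.42 at 6 h against -2.25 in vehicle rats.

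The RA time course asked how the deficient liver responds to RA itself. After 3 h Cyp26a1, Rarb and Dhrs3 were already higher than in vehicle rats. Cyp26a1 rose by 6.30 ± 0.94 (adjusted p = 0.0022), Rarb by 1.78 ± 0.29 (adjusted p = 0.00323) and Dhrs3 by 1.59 ± 0.25 (adjusted p = 0.0024), with 3 of 3 arrays above all vehicle arrays. Cyp2c22 rose by 3.76 ± 0.60. The nuclear receptor gene Nr0b2 (2.68 ± 0.42), Dact2 (3.78 ± 0.77), Snx21 (2.48 ± 0.47), Angptl8 (2.06 ± 0.29), Ppp1r3b (1.85 ± 0.31) and Bmp2 (1.63 ± 0.32) completed the largest rises. Lrat (3.55 ± 0.82, adjusted p = 0.122), Cyp26b1 (3.36 ± 0.79, adjusted p = 0.145) and Cyp3a9 (0.47 ± 0.42, adjusted p = 1) were not called. On vehicle replicate 2, Lrat (2.62) and Cyp2c22 (7.11) lay far above the other vehicle arrays.

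RA receptor targets were called higher in 3 of 24 cases at 3 h, or 5 adjusted over the list alone (median 0.127, camera adjusted p = 7.18e-05, and adjusted p = 0.442 with an estimated correlation). The wider retinoid list of 40 genes was called upward, with the same 3 genes called or 5 adjusted over the list alone, although its median was -0.00883 and its mean 0.404 (camera adjusted p = 0.0251). Drug-metabolising P450 genes (Cyp2c22 called of 24, 2 adjusted over the list alone, median 0.198, camera adjusted p = 0.00414) and lipogenesis genes (0 of 31 called, 0 adjusted over the list alone, median 0.274, camera adjusted p = 0.0116) lay higher. The adjusted p with an estimated correlation was 0.842 for these 3 lists. In total 22 probe sets were called, 21 higher and 1 lower, and without vehicle replicate 1 the number was 4. Without a trend in eBayes limma called 0, where 945 had an unadjusted p under 0.05 with it.

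At 6 h Cyp26b1 and Lrat were called as well, and Angptl4, Cyp8b1 and Lpin1 were among the genes that fell. Cyp26a1 rose by 8.67 ± 0.94 (adjusted p = 9.63e-06) and Cyp26b1 by 5.35 ± 0.79 (adjusted p = 0.000613), in 3 of 3 arrays. Cyp2c22 (4.38 ± 0.60), Lifr (4.24 ± 0.68), the chemokine gene Ccl24 (3.99 ± 0.71) and Lrat (3.95 ± 0.82, adjusted p = 0.0276) rose. So did Dact2 (3.81 ± 0.77), Igfbp2 (2.98 ± 0.51), Snx21 (2.97 ± 0.47), Nr0b2 (2.77 ± 0.42), Dhrs3 (1.62 ± 0.25) and Rarb (1.39 ± 0.29). Mycl (-3.91 ± 0.77), Smyd3 (-3.63 ± 0.71), Angptl4 (-2.25 ± 0.35), Pfkfb1 (-2.22 ± 0.45) and Onecut1 (-2.18 ± 0.41) fell. Further falls were in Cyp8b1 (-2.17 ± 0.38), Nrep (-2.07 ± 0.41), Clec14a (-2.05 ± 0.39), Osgin1 (-1.65 ± 0.28) and Lpin1 (-1.64 ± 0.32). Cyp3a9 was not called (1.09 ± 0.42, adjusted p = 0.724).

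RA receptor targets were called higher in 5 of 24 cases, or 6 higher and 1 lower adjusted over the list alone (median 0.2, camera adjusted p = 1.48e-06, and adjusted p = 0.198 with an estimated correlation). The retinoid list held the same 5 calls (5 higher and 1 lower adjusted over the list alone, median -0.0887, mean 0.473, camera adjusted p = 0.0375 upward). Drug-metabolising P450 genes lay higher (1 called, 4 adjusted over the list alone, median 0.251, camera adjusted p = 0.00916). Cholesterol synthesis genes lay lower (0 of 21 called, 0 adjusted over the list alone, median -0.429, camera adjusted p = 0.017). Stellate cell markers also lay lower (median -0.564, camera adjusted p = 0.0307). Their called member, Lrat, rose, with 1 higher and 3 lower adjusted over the list alone. With an estimated correlation, adjusted p was 0.749 for cholesterol synthesis and 0.638 for the other lists. In total 58 probe sets were called, 34 higher and 24 lower, with 141 after quantile normalization, 25 without vehicle replicate 3 and 5 without a trend in eBayes.

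At 10 h Cyp8b1, Cyp7a1, Fads1 and Fads2 were lower, while Cyp26a1 and Cyp26b1 stayed higher. Cyp8b1 fell by 5.31 ± 0.36 (39.7-fold, adjusted p = 9.27e-11), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 3.77 ± 0.82 (adjusted p = 0.0246), in 4 of 4 arrays each. Vehicle replicate 3 held 5.18 for Cyp7a1 against 0.85 and 0.99 on the others, and without it the change was -2.35 (adjusted p = 0.51). At 16 h Cyp7a1 averaged 4.59 against 2.34 in vehicle rats, and the clock gene Dbp averaged 1.46 in vehicle rats, -0.79 at 10 h and 3.02 at 16 h. Vehicle rats were killed at 0 h, so time of day moved with time since RA. Cyp26a1 (6.29 ± 0.88), Cyp26b1 (6.23 ± 0.74), Sult1c3 (4.81 ± 0.88), Cyp2c22 (4.61 ± 0.56) and Lrat (4.32 ± 0.77) rose by the largest amounts. Igfbp2 (2.85 ± 0.48), Adss1 (2.31 ± 0.42), Rpp21 (1.73 ± 0.27), Rab38 (1.69 ± 0.40) and Gnmt (1.49 ± 0.28) followed. Falls were also large in Dido1 (-4.17 ± 0.83), Mfsd2a (-2.51 ± 0.30), Cav2 (-2.20 ± 0.44) and Clec14a (-2.04 ± 0.37). They were smaller in Rapgef4 (-1.97 ± 0.33), Cldn3 (-1.87 ± 0.33), Hamp (-1.81 ± 0.25) and Hsd17b2 (-1.78 ± 0.34). Rarb (0.41 ± 0.27, adjusted p = 0.685), Dhrs3 (0.88 ± 0.23, adjusted p = 0.0962) and Cyp3a9 (1.19 ± 0.39, adjusted p = 0.219) were not called.

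Lipogenesis genes were called lower in 6 of 31 cases, or 13 adjusted over the list alone (median -0.68, camera adjusted p = 3.13e-06, and adjusted p = 0.455 with an estimated correlation). Among them were Fads1 (-1.27 ± 0.20), Fads2 (-1.27 ± 0.26), Thrsp (-1.39 ± 0.30) and Lpin1 (-1.38 ± 0.30). Cholesterol synthesis genes lay lower (median -0.48, camera adjusted p = 0.000693) with Fdps called (-1.55 ± 0.22), or 5 adjusted over the list alone. Heat shock and endoplasmic reticulum stress genes lay lower (median -0.43, camera adjusted p = 0.000693) with Herpud1 (-1.30 ± 0.25), Hsp90b1 (-1.03 ± 0.23) and Pdia4 (-1.26 ± 0.30) called, or 8 adjusted over the list alone. Kupffer cell markers lay lower (median -0.528, camera adjusted p = 0.00542) with 0 of 15 called, or 3 adjusted over the list alone. Bile acid genes had 3 called lower of 29, Cyp8b1, Cyp7a1 and Abcc2 (-1.17 ± 0.22), or 2 higher and 5 lower adjusted over the list alone, and were not called as a group (camera adjusted p = 0.171). RA receptor targets (3 higher and 2 lower, 6 and 4 adjusted over the list alone, median 0.153, camera adjusted p = 0.0195) lay higher. So did drug-metabolising P450 genes (1 and 1, 6 and 3 adjusted over the list alone, median 0.0483, camera adjusted p = 0.0223) and the P450 families 1 to 4 (1 higher, 4 and 4 adjusted over the list alone, median 0.091, camera adjusted p = 0.0379). The adjusted p with an estimated correlation was 0.518 for heat shock, 0.455 for Kupffer cells and RA receptor targets and 0.591 for cholesterol synthesis and both P450 lists. In total 141 probe sets were called, 31 higher and 110 lower, against 290 after quantile normalization (168 higher and 122 lower). The median of all probe sets shifted by -0.193. Without vehicle replicate 3 the number called was 19, without vehicle replicate 1 it was 382, and without a trend in eBayes it was 2.

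At 16 h 1701 probe sets were called lower than in vehicle rats, against 212 after quantile normalization and 113 without 16 h replicates 1 and 2, which stood apart from the other arrays. Cyp2c22 stayed 12.9-fold higher (3.68 ± 0.60, adjusted p = 0.000957). Cyp26b1 (2.84 ± 0.79), Lrat (2.68 ± 0.82) and Sult1c3 (4.37 ± 0.94) were higher. Of the 3 arrays, 2 lay above all vehicle arrays for Cyp26b1 and Sult1c3 and 1 for Lrat (1.55, 1.14 and 3.41, against 2.62 on vehicle replicate 2). Cyp26a1 was no longer called (2.86 ± 0.94, adjusted p = 0.0643), with 0.38, -2.71 and 4.16 on the 3 arrays. The retinoid metabolism genes Aldh1a1 (-1.35 ± 0.32), Dhrs4 (-0.93 ± 0.21) and Rdh11 (-1.21 ± 0.33) fell, and Scarb1 fell by 1.00 ± 0.28. Rarb (-0.53 ± 0.29, adjusted p = 0.298), Dhrs3 (-0.24 ± 0.25, adjusted p = 0.64) and Cyp3a9 (1.00 ± 0.42, adjusted p = 0.152) were not called, and for Rarb and Dhrs3 the sign turned after quantile normalization, to 0.08 and 0.37. Most of the other large rises were in genes near the detection floor in vehicle rats: Runx1t1, H2bc1, Epha8, Gpr162, Cfap100, Slc23a4, Hes2 and Pinlyp rose by 3.52 to 4.74, from vehicle means of -4.67 to -2.80. The largest falls were in Hivep1 (-4.65 ± 1.01), Ackr3 (-4.57 ± 0.61), Ppp1r13b (-4.55 ± 0.97), Ripk2 (-4.53 ± 0.85) and Pwwp3b (-4.44 ± 1.35). Next came Cyp27b1 (-4.32 ± 1.29), Dnmt1 (-4.24 ± 0.75), Ankrd10 (-4.20 ± 0.88), RT1-Bb (-4.16 ± 0.95) and Zdhhc13 (-4.03 ± 0.59).

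Fatty acid oxidation genes were called lower in 17 of 44 cases at 16 h, or 23 adjusted over the list alone (median -0.756, camera adjusted p = 0.000593), with Pdk4 at -1.51 ± 0.22 and Acot2 at -1.40 ± 0.28. Cholesterol synthesis genes were lower in 8 of 21 cases, or 14 adjusted over the list alone (median -0.853, camera adjusted p = 0.000888), with Hsd17b7 (-1.65 ± 0.43) and Mvk (-2.61 ± 0.69). Heat shock and endoplasmic reticulum stress genes were lower in 11 of 28 cases, or 12 adjusted over the list alone (median -0.653, camera adjusted p = 0.00941), with Hsp90b1 (-1.52 ± 0.25) and Pdia4 (-1.43 ± 0.32). Kupffer cell markers were lower in 4 of 15, or 7 adjusted over the list alone (median -0.733, camera adjusted p = 0.00941), with Lyz2 (-1.05 ± 0.28) and Clec4f (-0.73 ± 0.20). Adipocyte markers lay higher (median 0.443, camera adjusted p = 0.00941) with 0 of 12 called, also adjusted over the list alone. Adjusted p was, with an estimated correlation, 0.589 for oxidation, cholesterol synthesis and heat shock, 0.431 for Kupffer cells and 0.378 for adipocytes.

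Called members of other lists at 16 h included Igfbp1 (-2.51 ± 0.42), Got1 (-1.76 ± 0.27), Cdkn1a (-2.17 ± 0.51), Icam1 (-1.39 ± 0.31), Fads2 (-1.60 ± 0.28), Elovl2 (-1.86 ± 0.33), Slc27a2 (-1.13 ± 0.21) and Abcb4 (-1.11 ± 0.25). The clock genes Nfil3 (-2.14 ± 0.45) and Clock (-1.39 ± 0.34) and the early genes Mcl1 (-1.06 ± 0.23) and Ier5 (-1.15 ± 0.28) fell, but their lists were not called (camera adjusted p = 0.274 and 0.775). The inflammation genes Hamp (-1.76 ± 0.26), Steap4 (-2.05 ± 0.36) and Cxcl9 (-2.25 ± 0.46) fell. So did single markers of other cells, Col3a1 (-1.36 ± 0.23), Vim (-1.59 ± 0.30), Cd74 (-1.71 ± 0.27), RT1-Da (-0.92 ± 0.21), Eng (-2.72 ± 0.57) and Kdr (-0.97 ± 0.25), but the stellate, B cell and endothelial lists were not called (camera adjusted p = 0.0608, 0.0939 and 0.0939). Among hepatocyte and conjugating genes Tdo2 fell by 1.00 ± 0.25, and Uox (-0.68 ± 0.20), Gstm2 (-1.44 ± 0.26) and Gstm1 (-1.28 ± 0.23) fell too. Cyp2c7 (1.41 ± 0.28), Ifi27l2b (1.49 ± 0.27) and Igfbp2 (2.50 ± 0.51) rose. In total 1765 of 28869 probe sets were called, 64 higher and 1701 lower, against 323 after quantile normalization (111 higher and 212 lower). The median of all probe sets shifted by -0.392. Without 16 h replicates 1 and 2, 127 were called (14 higher and 113 lower), and without vehicle replicates 2 or 3 the number was 215 or 220. Without a trend in eBayes it was 40.

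**Figure D3:**
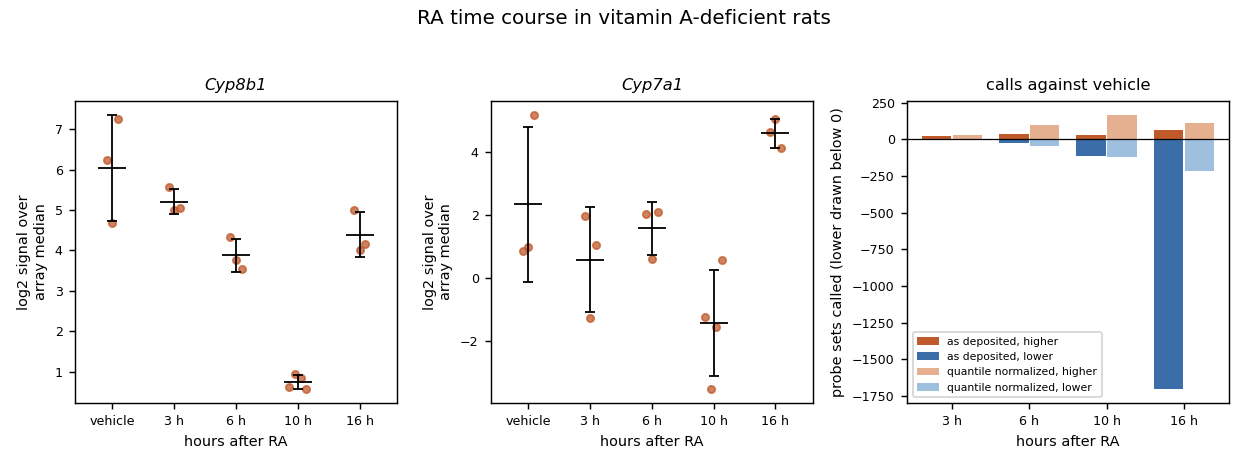
Log2 signal relative to the array median of Cyp8b1 and Cyp7a1 against hours after RA, with points for arrays and bars for the mean and SD, beside bars for the number of probe sets called higher (above 0) and lower (below 0) at each time, as deposited and quantile normalized. Cyp8b1 averages 0.74 at 10 h against 6.05 in vehicle rats.

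A test for a difference from vehicle at any of the RA times called 1384 probe sets (611 after quantile normalization and 614 without 16 h replicates 1 and 2). In the direct comparison of 16 h with 3 h, Rarb (-2.30 ± 0.29, adjusted p = 3.61e-05) and Dhrs3 (-1.83 ± 0.25, adjusted p = 8e-05) fell in 3 of 3 arrays, Cyp26a1 (-3.43 ± 0.94, adjusted p = 0.0215) fell in 2 of 3, and Nr0b2 (-2.37 ± 0.42) fell too. Without 16 h replicates 1 and 2 the Cyp26a1 difference was 0.12, and those of Cyp26b1, Lrat and Cyp2c22 were 1.39, 0.51 and 0.75. Cyp2c22 (-0.08 ± 0.60), Lrat (-0.87 ± 0.82), Cyp26b1 (-0.51 ± 0.79) and Cyp3a9 (0.52 ± 0.42) were not called, and the sign for Cyp2c22 turned after quantile normalization (0.16). Further falls of retinoid genes were in Aldh1a1 (-1.69 ± 0.32), Dhrs4 (-0.89 ± 0.21), Rbp7 (-3.23 ± 1.02), Rdh11 (-1.23 ± 0.33) and Scarb1 (-0.97 ± 0.28), while Rdh16 rose (4.38 ± 0.99). The other large rises were in Ooep, H2bc1, Scara5, Ms4a20, Cfap100, Gpr135, Tcf23, Shbg and Neurog3 (4.06 to 4.72), which had 3 h means of -5.02 to -3.37, near the floor. Large falls were in Ackr3 (-5.45 ± 0.61), Nedd1 (-5.33 ± 0.80), Hivep1 (-5.17 ± 1.01), Gdf15 (-5.01 ± 0.81) and Tsku (-4.56 ± 1.00). Next came Ripk2 (-4.39 ± 0.85), Zdhhc13 (-4.37 ± 0.59), Adgrg6 (-4.27 ± 1.01), Ppp1r13b (-4.12 ± 0.97) and Trim36 (-3.93 ± 0.81).

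Fatty acid oxidation genes were lower at 16 h than at 3 h in 19 of 44 cases, or 28 adjusted over the list alone (median -0.827, camera adjusted p = 1e-05), with Acot2 (-1.72 ± 0.28) and Ehhadh (-1.53 ± 0.25). Lipogenesis genes were lower in 10 of 31 cases, or 14 adjusted over the list alone (median -0.821, camera adjusted p = 0.0195), with Elovl2 (-2.17 ± 0.33) and Fads2 (-1.76 ± 0.28). Cholesterol synthesis genes were lower in 6 of 21, or 14 adjusted over the list alone (median -0.895, camera adjusted p = 0.0232), with Pmvk (-1.28 ± 0.27) and Insig1 (-1.87 ± 0.46). Heat shock genes were lower in 12 of 28 cases, or 16 adjusted over the list alone (median -0.82, camera adjusted p = 0.0169), with Hsp90b1 (-1.33 ± 0.25) and Xbp1 (-1.20 ± 0.23). Stellate cell markers were lower in 9 of 25 cases, or 11 adjusted over the list alone (median -1.18, camera adjusted p = 0.0471), with Col3a1 (-1.39 ± 0.23) and Colec11 (-1.45 ± 0.25). Kupffer cell markers were lower in 4 of 15, or 7 adjusted over the list alone (median -0.679, camera adjusted p = 0.0292), with C1qa (-1.12 ± 0.28). T and NK cell markers (median -0.047, mean 0.0941, camera adjusted p = 0.0261) and neutrophil markers (median 0.256, camera adjusted p = 0.0471) were called upward with none of their members called, also adjusted over the list alone. The adjusted p with an estimated correlation was 0.605 for oxidation and Kupffer cells, 0.733 for lipogenesis and cholesterol synthesis, 0.717 for heat shock and stellate cells and 0.256 for the leukocyte lists. The clock gene Dbp rose by 3.51 ± 0.72. Nfil3 (-2.46 ± 0.45), Cdkn1a (-3.30 ± 0.51), Irf1 (-2.98 ± 0.37), Dusp6 (-1.64 ± 0.25), Gadd45a (-1.82 ± 0.37), Hamp (-1.71 ± 0.26) and Steap4 (-1.77 ± 0.36) fell. Rtp4 (-1.20 ± 0.25), Cd74 (-1.46 ± 0.27), RT1-Ba (-1.62 ± 0.37) and Got1 (-1.91 ± 0.27) fell as well. So did Pc (-1.59 ± 0.34), Tat (-1.32 ± 0.35), Akr1d1 (-1.54 ± 0.29) and Eng (-2.49 ± 0.57). Smaller falls were in Kdr (-1.05 ± 0.25), Clec4f (-0.75 ± 0.20), Igfals (-1.22 ± 0.30), Uox (-0.78 ± 0.20), Cyp4f1 (-1.17 ± 0.23), Cyp4v3 (-1.20 ± 0.25), Gstm1 (-1.43 ± 0.23) and Gstm2 (-1.56 ± 0.26). Slco1a1 fell by 1.00 ± 0.23 and Ugt2b1 by 1.00 ± 0.22. In total 2513 probe sets were called, 86 higher and 2427 lower, against 356 after quantile normalization (97 higher and 259 lower), and the median of all probe sets shifted by -0.424. Without 16 h replicates 1 and 2 the number called was 191, and without a trend in eBayes it was 88.

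The intravenous experiment followed the first 90 min after a smaller RA dose in rats of ordinary vitamin A status. At 30 min 18 genes were called, of which 7 were immediate early genes and 2 clock genes. The G protein regulator gene Rgs1 rose by 3.73 ± 0.53 (adjusted p = 0.008), Noct by 3.54 ± 0.38 (adjusted p = 0.00244), and the chemokine genes Cxcl1 by 3.53 ± 0.44 and Cxcl2 by 3.04 ± 0.52, in 3 of 3 arrays. Fos (2.65 ± 0.34), Tsku (2.44 ± 0.35), Coq10b (2.08 ± 0.36), Gadd45b (2.02 ± 0.28), Bhlhe40 (1.96 ± 0.27), Tcim (1.87 ± 0.26), Egr1 (1.44 ± 0.16), Cebpb (1.44 ± 0.23) and Nfkbia (1.36 ± 0.16) rose. Cep350 (-1.06 ± 0.15) was the only named gene to fall. Cyp26a1 was 8.3-fold above vehicle in 3 of 3 arrays but not called (3.05 ± 0.56, adjusted p = 0.0693), and neither were Cyp26b1 (0.70 ± 0.23), Lrat (0.36 ± 0.18), Rarb (-0.20 ± 0.18), Dhrs3 (-0.11 ± 0.15), Cyp2c22 (0.49 ± 0.16) and Cyp3a9 (-0.20 ± 0.53). After quantile normalization Dhrs3 turned to 0.04.

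Immediate early genes were called higher in 7 of 39 cases, or 15 adjusted over the list alone (median 0.706, camera adjusted p = 4.34e-28). Clock genes were called higher in 2 of 22 cases, or 3 adjusted over the list alone (median 0.291, camera adjusted p = 2.41e-07). Of 20 glucocorticoid-responsive genes 0 were called by limma, or 9 higher adjusted over the list alone (median 0.437, camera adjusted p = 7.95e-11). These 3 calls held with an estimated correlation. Lists that lay higher without that support were gluconeogenesis (0 called, 4 adjusted over the list alone, median 0.134, camera adjusted p = 0.000637) and the acute phase (Cebpb called, 1 adjusted over the list alone, median 0.066, camera adjusted p = 1.98e-06). The drug-metabolising P450 list lay higher (Gadd45b, not a P450, called, 1 and 1 adjusted over the list alone, median 0.0541, camera adjusted p = 0.026). The interferon (median 0.332, camera adjusted p = 1.94e-09), growth hormone (median 0.0878, camera adjusted p = 0.0138) and hepatocyte lists (median 0.0702, camera adjusted p = 0.000819) lay higher with none called, also adjusted over the list alone. The same held for the stellate cell (median 0.0576, camera adjusted p = 0.0462), T and NK cell (median 0.16, camera adjusted p = 0.0174) and B cell lists (median 0.32, camera adjusted p = 0.0207). With an estimated correlation, adjusted p was 0.27 for gluconeogenesis, interferon and T cells, 0.379 for the acute phase and B cells, 0.475 for P450 and growth hormone genes, 0.531 for stellate cells and 0.517 for hepatocytes. Without vehicle replicate 1 the medians of the P450 and hepatocyte lists were -0.146 and -0.075. In total 20 of 22763 probe sets were called, 19 higher and 1 lower, and the median of all probe sets shifted by -0.103 (-0.109 at 90 min). Without 1 array the count ran from 9 (30 min replicate 1) to 36 (vehicle replicate 2), and without a trend in eBayes it was 1. Vehicle rats were killed at 0 min, so time since anaesthesia and surgery moved together with time since RA.

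At 60 min Cyp26a1, Cyp26b1 and Cyp2c22 were called higher, and Pdk4, Acot1 and Ehhadh lower. Cyp26a1 rose by 5.43 ± 0.56 (43.2-fold, adjusted p = 0.000817), Cyp26b1 by 2.76 ± 0.23 (adjusted p = 0.000105) and Cyp2c22 by 1.28 ± 0.16 (adjusted p = 0.00266), in 3 of 3 arrays. Cxcl1, near the floor in vehicle rats, rose by 6.31 ± 0.44 (adjusted p = 1.78e-05), with Rgs1 (3.78 ± 0.53), Tsku (3.30 ± 0.35), Cxcl2 (3.07 ± 0.52), Noct (3.03 ± 0.38), Dbp (2.99 ± 0.53), Gpr108 (2.95 ± 0.58) and Zfp354a (2.75 ± 0.41). Falls were largest in the clock gene Npas2 (-3.36 ± 0.61), Acot1 (-2.85 ± 0.50), Pdk4 (-2.39 ± 0.31), Igfbp1 (-2.27 ± 0.40), Slc34a2 (-2.20 ± 0.32), Osgin1 (-1.96 ± 0.35), Ehhadh (-1.91 ± 0.38), Chka (-1.57 ± 0.28), Cbx7 (-1.56 ± 0.31) and Lgalsl (-1.55 ± 0.28). Lrat (0.86 ± 0.18, adjusted p = 0.0587), Rarb (0.40 ± 0.18, adjusted p = 0.47), Dhrs3 (-0.02 ± 0.15) and Cyp3a9 (-0.03 ± 0.53) were not called, and the last 2 turned to 0.11 and 0.10 after quantile normalization.

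Fatty acid oxidation genes were called lower in 4 of 45 cases, or 17 adjusted over the list alone (median -0.323, camera adjusted p = 2.86e-08, and adjusted p = 0.163 with an estimated correlation), with Acot3 (-1.22 ± 0.21) beside Pdk4, Acot1 and Ehhadh. Clock genes were called in 8 of 22 cases, 6 higher and 2 lower, or 9 and 4 adjusted over the list alone (median 0.423, camera adjusted p = 3.09e-06). Per1 (1.63 ± 0.23), Bhlhe40 (1.90 ± 0.27) and Usp2 (2.37 ± 0.35) were among the risers. Immediate early genes were called higher in 4 of 39 cases, or 11 higher and 1 lower adjusted over the list alone (median 0.455, camera adjusted p = 8.26e-13), with Nfkbia (1.39 ± 0.16), Rhob (1.47 ± 0.22) and Zfp36 (0.82 ± 0.15). Both of these held with an estimated correlation. RA receptor targets (2 higher and 1 lower, 5 and 3 adjusted over the list alone, median 0.0973, camera adjusted p = 0.00285) and cholesterol synthesis genes (Insig1 at 1.18 ± 0.17, 6 adjusted over the list alone, median 0.302, camera adjusted p = 4.91e-06) lay higher. The same was seen in acute phase genes (Cebpb at 1.23 ± 0.23, 3 adjusted over the list alone, median 0.234, camera adjusted p = 1.62e-11) and interferon genes (Oasl at 1.30 ± 0.24, 2 adjusted over the list alone, median 0.446, camera adjusted p = 9.16e-11). So did glucocorticoid-responsive genes (1 and 1, 4 and 2 adjusted over the list alone, median 0.303, camera adjusted p = 4.51e-05) and drug-metabolising P450 genes (1 called, 4 and 2 adjusted over the list alone, median 0.0896, camera adjusted p = 0.0104). Growth hormone genes also lay higher (Igfbp1 lower, 3 and 1 adjusted over the list alone, median 0.147, camera adjusted p = 0.0113), and so did neutrophil markers (0 called, 1 adjusted over the list alone, median 1.01, camera adjusted p = 0.00883). Erythroid (median 0.316, camera adjusted p = 0.0113) and hepatocyte markers (median 0.234, camera adjusted p = 2.06e-08) lay higher with none called, also adjusted over the list alone. The adjusted p with an estimated correlation was 0.163 for RA receptor targets, the acute phase, glucocorticoid and neutrophil lists, 0.184 for cholesterol, interferon, erythroid and hepatocyte lists, 0.343 for P450 genes and 0.349 for growth hormone genes. In total 88 probe sets were called, 50 higher and 38 lower, against 90 after quantile normalization (64 higher and 26 lower). Without vehicle replicate 1 the number was 25, and without a trend in eBayes it was 2.

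At 90 min the RA receptor targets lay higher as a group, and the chemokine genes Cxcl1, Cxcl10 and Ccl2 were called. Cyp26a1 rose by 5.61 ± 0.56 (49-fold, adjusted p = 0.000149), Cyp26b1 by 3.48 ± 0.23 (adjusted p = 4.6e-06) and Cyp2c22 by 1.81 ± 0.16. Rarb rose by 1.45 ± 0.18 (adjusted p = 0.0013) and Lrat by 0.88 ± 0.18 (adjusted p = 0.0476), and all 5 genes lay above vehicle in 3 of 3 arrays. Cxcl1, near the floor in vehicle rats, rose by 7.82 ± 0.44 (adjusted p = 9.69e-07). Tsku (4.16 ± 0.35), Cxcl10 (4.09 ± 0.43) and Ccl2 (3.66 ± 0.46) rose. So did Tnfaip3 (3.12 ± 0.23), Zfp354a (2.97 ± 0.41), Rgs1 (2.90 ± 0.53) and Usp2 (2.86 ± 0.35). Septin8 (-2.32 ± 0.44), Rnf125 (-1.91 ± 0.33), Nfil3 (-1.77 ± 0.23), Ccng2 (-1.69 ± 0.25) and Ldaf1 (-1.61 ± 0.32) fell. Smaller falls included AKR1C3l1 (-1.57 ± 0.26), the retinol-oxidising Adh4 (-1.32 ± 0.27), Id4 (-1.23 ± 0.18), Hells (-1.18 ± 0.22), Brd10 (-1.16 ± 0.22) and Cd36 (-0.87 ± 0.18). Dhrs3 (0.25 ± 0.15, adjusted p = 0.594) and Cyp3a9 (-1.61 ± 0.53, adjusted p = 0.272) were not called.

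RA receptor targets were called higher in 5 of 21 cases, or 5 higher and 1 lower adjusted over the list alone (median 0.177, camera adjusted p = 1.25e-06), with Icam1 (2.19 ± 0.24) beside Cyp26b1, Cyp26a1, Rarb and Lrat. Immediate early genes were called in 7 of 39 cases, or 12 adjusted over the list alone (median 0.437, camera adjusted p = 4.87e-13), with Nfkbia (2.34 ± 0.16) and Gadd45a (1.83 ± 0.25). Clock genes were called in 4 of 22 cases, or 6 and 2 adjusted over the list alone (median 0.347, camera adjusted p = 7.25e-05), with Per2 (2.34 ± 0.39) and Noct (2.04 ± 0.38) higher and Nfil3 lower. These 3 held with an estimated correlation. That made 8 of 34 list calls in this experiment, against 0 of 19 in the diet experiment and 0 of 29 in the RA time course. Interferon genes (Cxcl10, Irf1 at 1.95 ± 0.34 and Oasl at 1.19 ± 0.24, 4 adjusted over the list alone, median 0.0598, camera adjusted p = 8.33e-05) and acute phase genes (Cebpb at 1.53 ± 0.23 and Cebpd at 1.29 ± 0.26, 6 adjusted over the list alone, median 0.176, camera adjusted p = 3.96e-09) lay higher. The same was seen in glucocorticoid-responsive genes (Fkbp5 at 1.49 ± 0.24, 5 adjusted over the list alone, median 0.21, camera adjusted p = 1.81e-06) and neutrophil markers (S100a9 at 2.30 ± 0.37, 2 of 6 adjusted over the list alone, median 1.28, camera adjusted p = 0.00195). Drug-metabolising P450 genes (Cyp2c22 called, 3 and 2 adjusted over the list alone, median 0.102, camera adjusted p = 0.00255) and hepatocyte markers (0 called, 0 adjusted over the list alone, median 0.121, camera adjusted p = 3.34e-06) lay slightly higher. Adjusted p was, with an estimated correlation, 0.492 for interferon, 0.242 for the acute phase, 0.0633 for glucocorticoid-responsive genes, 0.115 for neutrophils and 0.359 for the P450 and hepatocyte lists. In total 115 probe sets were called, 76 higher and 39 lower, against 114 after quantile normalization (90 higher and 24 lower), and 125 differed from vehicle at any time. Without vehicle replicate 1 the number at 90 min was 43, and without a trend in eBayes it was 28.

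**Figure D4:**
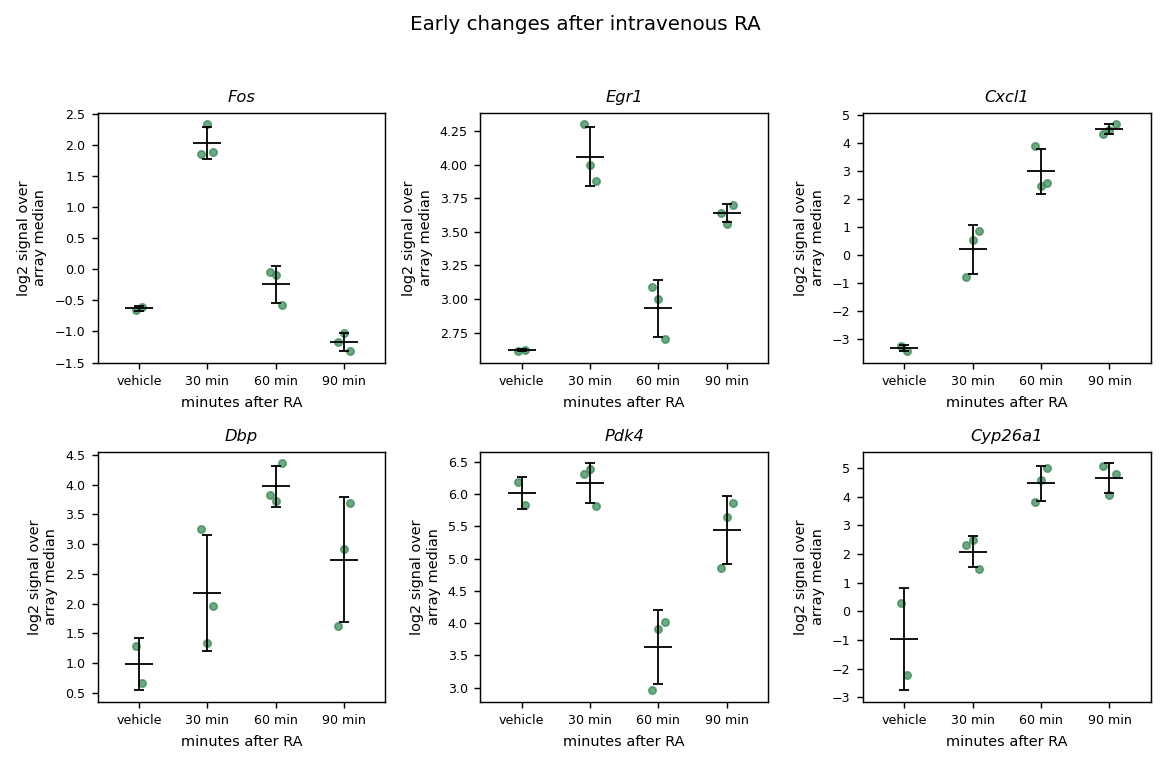
Log2 signal relative to the array median of Fos, Egr1, Cxcl1, Dbp, Pdk4 and Cyp26a1 against minutes after intravenous RA, with points for arrays and bars for the mean and SD. Fos averages 2.03 at 30 min against -0.63 in vehicle rats, while Cxcl1 averages 4.50 at 90 min against -3.32.

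Genes that differed between supplemented and deficient diets were then followed in the RA experiments, which used other rats. The 65 genes higher with retinol lay higher at 3, 6 and 10 h after RA, with medians of 0.447, 0.616 and 0.484 (camera adjusted p = 4.41e-21, 9.44e-26 and 1.77e-24, and adjusted p = 0.0992, 0.0876 and 0.0876 with an estimated correlation). At 16 h their median was 0.013, with 34 of 65 above 0. Camera called it (adjusted p = 2.55e-07, and 0.319 with an estimated correlation) against -0.392 for all probe sets. Fry did not (adjusted p = 0.774, or 0.197 at 3, 6 and 10 h). Without deficient replicate 4 the 16 h median was -0.432 (adjusted p = 0.252). Relative to the mean of vehicle replicates 1 and 3, the set median was -0.31 and 0.31 on these, 0.90 on replicate 2 and 0.71 to 0.84 at 3 h. Of these 65, 6 were called higher at 3 h (Cyp26a1, Cyp2c22, Rarb, Angptl8, Ppp1r3b and Avpr1a), 8 at 6 h (among them Lrat, Lifr, Oaf and Rpp21), 10 at 10 h (among them Sult1c3, Adss1, Rab38 and Eci3) and 7 at 16 h, and none were called lower. The 11 genes lower with retinol had medians of 0.121, -0.567, -1.151 and -1.398 (camera adjusted p = 0.872, 0.0169, 5.57e-07 and 0.000206). Cyp8b1 was lower from 6 h, Fabp7 from 10 h, and Gstm2, Rab30, Cyp17a1 and Cela1 at 16 h. With an estimated correlation the 10 h and 16 h falls held (adjusted p = 0.00279 and 0.012), and adjusted p for the lower set at 6 h was 0.0876. Over 13053 genes the diet and RA changes were hardly related (Spearman correlations across genes, which are not independent replicates, of 0.045, 0.027, 0.063 and -0.027).

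In the first 90 min after intravenous RA the higher set was called at 60 min (median 0.028, camera adjusted p = 0.0101, and adjusted p = 0.117 with an estimated correlation). A higher set formed anew without deficient replicate 4 lay downward and was not called (median -0.158, adjusted p = 0.234). The one formed anew with arrayWeights was not called either. Of the 65 genes, Insig1, Ppp1r3b, Cyp26a1 and Cyp2c22 were called higher at 60 min. At 90 min the same 4 genes, Lrat and Rarb were called higher, and the set was not (median -0.137, mean 0.057, adjusted p = 0.135). The lower set was called upward at 30 min with a median of -0.012 and a mean of 0.240 (camera adjusted p = 0.037, and adjusted p = 0.0992 with an estimated correlation). A lower set formed anew without supplemented replicate 1 lay downward (median -0.213). The higher set was not called at 30 min (median -0.198, adjusted p = 0.935), but in 6 alternatives its direction turned and it was called, for example with a replicate block (median 0.203, adjusted p = 0.00019). The other tests gave adjusted p = 0.102 for the lower set at 60 min (median -0.292) and 0.935 for it at 90 min (median -0.070).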

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

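The gap rule for a single array far from the others of its group, the comparison of 16 h with 3 h and the alternatives in the next part, apart from those named there, were fixed before the data were examined. Of the tests of explanations below, the array-scaling and single-array tests of the 16 h calls, the Cyp26a1 test of vehicle replicate 2 and the tests on Xist were chosen after the result was seen.

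An array lay far from the others of its group in 18 of 290 tested groups of values (6.21%, about 1 in 20 by chance). Groups under 4 arrays were not tested, so outside the diet experiment only 10 h was. In adequate replicates 2, 1, 3 and 5 these were, in turn, Cpa1 (4.27), Cyp26a1 (1.26), Fdft1 (5.80) and Slco1b2 (5.54). Deficient replicates 5 and 3 gave Sult1c3 (-3.82) and Cyp8b1 (7.32). At 10 h after RA, replicate 2 gave 7 of them: Gnmt (7.86), Herpud1 (3.38), Ankrd10 (-2.92), Zdhhc13 (0.20), Scara5 (-5.37), Shbg (-2.82) and Slco1a1 (3.99). Replicate 1 at 10 h gave Pfkfb1 (2.34), Lpin1 (2.58), Sult1c3 (1.57) and Hsp90b1 (5.74), and replicate 3 gave Dact2 (0.54).

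By a limma test 2513 probe sets differed between 16 h and 3 h after RA. So did 52 of 72 named genes, 48 lower and 4 higher at 16 h, which choosing most of them on these arrays favoured. Higher were H2bc1 (4.58), Cfap100 (4.30), Epha8 (3.98) and Slc23a4 (3.76). Lower by more than 2 were Ackr3 (-5.45), Hivep1 (-5.17), Ripk2 (-4.39), Zdhhc13 (-4.37), Ppp1r13b (-4.12), Dact2 (-3.65), Dnmt1 (-3.44), Cyp26a1 (-3.43), Cdkn1a (-3.30), Ankrd10 (-3.11), Snx21 (-2.75), Mvk (-2.55), Eng (-2.49), Nfil3 (-2.46), Nr0b2 (-2.37), Rarb (-2.30) and Elovl2 (-2.17). Lower by 1.4 to 2 were Got1 (-1.91), Dhrs3 (-1.83), Steap4 (-1.77), Fads2 (-1.76), Acot2 (-1.72), Hamp (-1.71), Bmp2 (-1.70), Aldh1a1 (-1.69), Cxcl9 (-1.62), Clock (-1.57), Gstm2 (-1.56), Ppp1r3b (-1.52), Cd74 (-1.46), Icam1 (-1.44) and Gstm1 (-1.43). Lower by less were Col3a1 (-1.39), Hsp90b1 (-1.33), Pdia4 (-1.30), Rdh11 (-1.23), Pdk4 (-1.21), Vim (-1.17), Abcb4 (-1.13), Mcl1 (-1.09), Slc27a2 (-1.06), Kdr (-1.05), Ier5 (-1.04), Scarb1 (-0.97), Dhrs4 (-0.89), RT1-Da (-0.81), Uox (-0.78) and Clec4f (-0.75).

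Of the probe sets called at 16 h against vehicle, 96.4% were lower. After quantile normalization 65.6% were lower, so scaling of arrays with different value distributions and a fall of many transcripts cannot be told apart for this share. With replicate 3 as the only 16 h array 113 were called lower, against 4406 with replicate 1 and 2393 with replicate 2, each with the lone array assumed to vary like the other groups. The number depended on replicates 1 and 2, which stood apart, and on the controls, since 215 and 220 were called in all without vehicle replicates 2 and 3. The vehicle rats were killed at 0 h, so no biological explanation, such as time of day, was tested. What set replicates 1 and 2 apart stays open.

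In the RA time course, genes that rose with dietary retinol differed between the vehicle arrays. On replicate 2, 62 of 65 lay above the mean of the others (median 0.90), and on replicate 1 only 5 (median -0.91). Cyp26a1, at -1.14 against at least 3.40, excluded an exchange of replicate 2 with a 3, 6 or 10 h array. On replicate 2 genes that fell with retinol lay at -0.59 from the mean of the other vehicles, and below each (-0.30 and -0.55). The nearest 16 h array lay at -1.02, with array-wide shifts left in, so a 16 h exchange stays open. The rising genes' excess fell from 0.90 to 0.55 after quantile normalization, so scaling and a difference of the rat cannot be told apart in size. A rat richer in retinol, or an unusual replicate 1 (GAPDH 3' to 5' difference 0.95, other time course arrays at most 0.78), stays open.

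On vehicle replicate 1 of the intravenous experiment, 4 of 4 Xist probe sets lay under those of all other arrays of that experiment, so failure of a single probe set was excluded. A male liver was excluded: Cyp2c12, higher in female rats, lay at -0.22 and the male-specific Cyp2c11 at 0.15 from the median of the other arrays, and 0 of 3 Y-linked probe sets lay above them. No other biological explanation was tested, and the source stays open.

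Regrouping the arrays at random tested the counts of called probe sets. For deficient against adequate few splits, 2 of 100 with the real one included, gave as many as the real 299. The highest other split, 535, exchanged deficient replicate 4 with adequate replicate 4, so chance was not excluded. The real split gave the most at 10 h (141, highest other 15, 1 of 35 splits). So it did for any RA time (1384, highest other 142, 1 of 100 splits). For marginal against adequate, where 0 were called by limma (916 at an unadjusted p under 0.05), 100 of 100 splits gave as many and the highest other was 3. The 10 splits were too few for 3 h (22, highest other 0, 1 split as large), 6 h (58, highest other 5, 1 split), 16 h (1765, highest other 2947, 2 splits) and 16 h against 3 h (2513, highest other 2, 1 split). The 2947 came from 16 h replicates 1 and 2 with vehicle replicate 1, which pointed to a structure of the samples.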

How the results depend on the processing

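Offsets on back-transformed values and the fits without the arrays that stood apart were chosen after seeing the data, and the other alternatives were fixed before. In the counts below the order is diet experiment, RA time course, intravenous experiment, and for each changed value the cause was not tested, except that fits on 1 run or without arrays use fewer arrays and the 1.5-fold minimum removes calls by construction.

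Without a trend in eBayes, limma called 64 for deficient, 20 for supplemented against deficient, 19 for the diet trend, 0 at 3 h, 5 at 6 h, 2 at 10 h, and 40 at 16 h. It called 88 for 16 h against 3 h, 41 at any time, and 1, 2 and 28 at 30, 60 and 90 min and 17 at any of these. Lists called in the RA time course came to 12, and diet gene sets there to 4. With arrayWeights the counts were 10 for supplemented against adequate, 187 against deficient, 162 for the trend, 63, 272, 1296 and 3289 at 3, 6, 10 and 16 h and 2815 at any time, and 0 diet gene sets were called by camera in the intravenous experiment. Quantile normalization gave 166 for the trend, 34, 141, 290 and 323 at 3, 6, 10 and 16 h, 356 for 16 h against 3 h and 611 at any time. A 1.5-fold minimum gave 52 for the trend. No filter gave 1 diet gene set in the intravenous experiment. An offset at the 20th percentile gave 36 at 3 h, and an offset of 1 median signal gave 42, 95 and 277 at 3, 6 and 10 h and 190 at any time to 90 min. Camera with an estimated correlation called 0, 0 and 8 lists, 2 diet gene sets in the RA time course and 0 in the intravenous experiment, and fry called 8 lists for diet, 9 lists in the intravenous experiment, and 2 and 1 diet gene sets.

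With the replicate number as a block, 0 were called by limma for supplemented against adequate (1003 at an unadjusted p under 0.05 in the fit without it), 15 against deficient, 13 for the trend, 72 at 10 h and 51 at 60 min, and 4 diet gene sets in the RA time course. Arrays of the same number were not paired: mean correlations of residuals were -0.051, 0.003 and 0.001. Without the run covariate 167 were called for deficient. The first run alone gave 61 for deficient, 57 for supplemented against deficient, 44 for the trend and 4 diet gene sets in the intravenous experiment, and the second 1 for marginal. Without the arrays that stood apart the counts were 86, 58 and 61 for deficient, supplemented against deficient and the trend, 46, 132, 457 and 127 at 3, 6, 10 and 16 h, 191 for 16 h against 3 h and 614 at any time, with 17 lists in the RA time course.

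Leaving out 1 array gave 156 (adequate 2) to 1493 (deficient 4) for deficient, also 164 (adequate 1), 175 (deficient 5) and 192 (deficient 1). Ranges were 0 to 0 for marginal by limma (916 at an unadjusted p under 0.05 with all arrays), 3 to 14 for supplemented against adequate (14 without supplemented 1, 10 without 2). They were for supplemented against deficient 43 (supplemented 1) to 430 (deficient 4), also 59 (supplemented 2) and 70 (deficient 5), and 46 (supplemented 1) to 323 (deficient 4) for the trend, also 58 (supplemented 2). At 3 h the range was 4 (vehicle 1) to 40 (vehicle 2), with 8, 11 and 12 without 3 h arrays 1, 2 and 3, 10 without vehicle 3, and 36 and 35 without 16 h arrays 1 and 3. At 6 h it was 25 (vehicle 3) to 87 (16 h 3), with 26 without 6 h arrays 1 or 3. At 10 h it was 19 (vehicle 3) to 382 (vehicle 1), with 72, 66 and 79 without 10 h arrays 2, 3 and 4 and 243 and 286 without 16 h arrays 1 and 3. At 16 h it was 215 (vehicle 2) to 4498 (16 h 3), with 513 and 1086 without 16 h arrays 1 and 2, 3216 without vehicle 1 and 220 without vehicle 3. For 16 h against 3 h it was 727 (3 h 1) to 5044 (16 h 3), with 1326 and 1023 without 3 h arrays 2 and 3 and 1003 and 1577 without 16 h arrays 1 and 2. At any RA time it was 753 (3 h 1) to 3638 (16 h 3), with 851 without 3 h 3, 814 and 798 without 16 h arrays 1 and 2, 2419 without vehicle 1 and 835 without vehicle 3.

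In the intravenous experiment leaving out 1 array gave 9 (30 min 1) to 36 (vehicle 2) at 30 min and 25 (vehicle 1) to 99 (90 min 1) at 60 min, also 42 (vehicle 2) and 37 (60 min 3). At 90 min it gave 43 (vehicle 1) to 114, also 58 (90 min 2) and 65 (vehicle 2), and at any time 78 (vehicle 1) to 141. Lists called ranged from 13 to 31 (supplemented 1) for diet, 23 to 38 for the time course and 20 (vehicle 1) to 46 (vehicle 2) in the intravenous experiment. Diet gene sets ranged from 5 to 7 and from 1 to 4 (4 without supplemented 2, 1 without adequate 5, deficient 1, marginal 2, 30 min 3 or 60 min 1). Of called named genes 51 of 93, 100 of 189 and 55 of 80 lost their call at least once without 1 array, and 0 reversed. Without a trend in eBayes 67 of 93, 165 of 189 and 68 of 80 lost it. Without the arrays that stood apart 36 of 93 for diet and 97 of 182 in the time course lost it, and 1 called gene reversed. Where 1 supplemented, vehicle or 16 h array was left, the lone sample was assumed to vary like the other groups.

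Signs turned as follows. For marginal, Lrat (-0.12) was 0.05 with the replicate block, 0.12 in the first run and -0.19 to 0.03 (adequate 2) without 1 array. Dhrs3 (-0.08) was 0.01 in the first run and -0.12 to 0.01 (adequate 1) without 1 array, and Rarb (0.20) -0.10 in the second run, where the direction of the cholesterol list turned at a median of -0.068. At 16 h Rarb (-0.53) was 0.08 with quantile normalization and 0.09 without the arrays that stood apart, and Dhrs3 (-0.24) 0.37 and 0.21. For 16 h against 3 h Cyp2c22 (-0.08) was 0.16 with quantile normalization, 0.75 without the arrays that stood apart and 0.14, 0.11 and -0.50 without 16 h arrays 1, 2 and 3. Cyp26a1 (-3.43) was 0.12, Cyp26b1 (-0.51) 1.39 and Lrat (-0.87) 0.51 without those that stood apart, and Cyp26b1 was 0.33 and -1.47 without 16 h arrays 2 and 3. Cyp3a9 at 3 h (0.47) was -0.22 without vehicle 1. In fry the immediate early list turned at 16 h (median -0.494), as did T and NK cells for 16 h against 3 h (-0.047).

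In the intravenous experiment with quantile normalization Dhrs3 was 0.04 at 30 min and 0.11 at 60 min, and Cyp3a9 0.10 at 60 min. At 60 min Dhrs3 was 0.01 and 0.02 and Cyp3a9 0.15 and 0.17 without vehicle 2 and 60 min 1, and Cyp3a9 was 0.02 and -0.29 without 60 min arrays 2 and 3. At 30 min Cyp3a9 was 0.10, -0.92 and 0.21 without 30 min arrays 1, 2 and 3, and the P450 and hepatocyte lists were -0.146 and -0.075 without vehicle 1 and 0.164 and 0.243 at the highest. The higher diet set at 30 min (-0.198) was 0.090 in the first run, 0.128 without a trend, 0.203 with the replicate block, 0.130 without the arrays that stood apart, and 0.092 and -0.014 without supplemented 1 and 2. Camera did not call it with all arrays (adjusted p = 0.935) and called it under these 6 alternatives (adjusted p = 1.51e-05 to 0.0213) and without deficient 4 (0.00339). The lower set (-0.012) was -0.213 without supplemented 1. Without 1 diet array the higher set ranged from -0.432 to 0.441 at 16 h, from -0.158 to 0.085 at 60 min and from -0.210 to 0.153 at 90 min, the lowest each without deficient 4.

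No value came from the offset planned for linear values, from the supplemented group in the second run, or for the lists with a random run or a fold minimum. The floor limits falls of weak probe sets, since the median signal was 10.0 to 69.8 times the floor.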

Other observations

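The 2 runs of identifiers in the diet experiment differed in genes of the circadian clock and in Cyp7a1, in a comparison chosen after the result was seen. In the second run Usp2 (4.16 ± 0.38, adjusted p = 4.64e-09), Cyp7a1 (3.79 ± 0.21, adjusted p = 1.41e-13), Dbp (3.08 ± 0.36) and Per2 (2.20 ± 0.26) were higher. Bmal1 (-1.10 ± 0.21), Cyp2c22 (-1.15 ± 0.23) and Dhrs3 (-0.76 ± 0.13) were lower, and Cyp8b1 was not called (0.26 ± 0.18, adjusted p = 0.394), over 12 and 8 arrays with diet in the fit. Limma called 3755 of 27595 probe sets, 950 higher and 2805 lower.

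Clock genes lay higher in the second run (6 higher and 5 lower of 23, median 0.375, camera adjusted p = 0.000474), as did immediate early genes (8 and 2 of 41, median 0.372, adjusted p = 5.73e-05) and glucocorticoid-responsive genes (5 and 2 of 20, median 0.320, adjusted p = 0.00216). Kupffer cell markers were lower in 10 of 15 cases (median -0.749, camera adjusted p = 1.85e-06), interferon genes in 12 of 41, acute phase genes in 7 of 30 and B cell markers in 4 of 12 (adjusted p = 0.0402 each). With an estimated correlation, adjusted p was 0.248 for clock, immediate early, glucocorticoid, Kupffer and B cell lists and 0.823 for the others. The time of day at which the rats were killed was not given.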
